A study of Mus musculus with 12 samples.

How the data were processed

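Polyadenylated RNA from mouse CD8 T cells was sequenced in 12 libraries, 3 for each combination of cell state (naive or stimulated) and treatment (Control or DEX). The series title names perinatal exposure to a stress hormone as the treatment. Naive cells came from OT-I mice, whose T cells carry a transgenic receptor for an ovalbumin peptide, and were gated as naive CD8 cells by surface markers, among them absence of CD44, while stimulated cells were gated as CD8-positive and CD4-negative. Spleen and/or lymph nodes were the tissue source, with magnetic enrichment of T cells before the sort, per the labels' protocols. Libraries followed a strand-specific poly(A) protocol, also per the labels' protocols. The labels give neither the dose and timing of the treatment, nor the stimulus, nor the sex of the mice. They call the samples replicates without saying that each came from another animal, so the p-values measure the spread between these samples, which may be technical.

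The authors deposited 1 table of gene values for each state. The submitters' processing notes name STAR 2.5.3a, a read aligner, Partek, a commercial analysis suite, and the mouse build GRCm38 (mm10). The quantifier, the normalization, the use of strand, the row filter and the unit are not given in the sources used here. The deposited values were taken to be counts-per-million values (CPM) of a library total, with 0.0001 added to each by the authors: after this offset was removed, 23.2 to 63.1% of a library's values under 50 reads lay within 0.02 of a whole multiple of a single step, taken as 1 read, where evenly spread values give 4%. The same step gave 22.1 to 50.1% among the genes with transcripts up to the median length and 24.0 to 77.8% among longer ones. This unit is an inference from the values, and most low values of the naive libraries lay off the step. The listed genes summed to 57.9 to 82.4% of the full CPM total, so the total behind the CPM was larger than the listed genes. There were 12191 genes listed for naive and 16506 genes for stimulated cells. Because so many values were not whole, read counts were not recovered, and no test for counts was run. The step gave an inferred depth of 14.0 to 23.6 M reads per naive library and 6.73 to 12.0 M per stimulated library. A value of 3 reads then corresponds to 0.127 to 0.214 CPM in the naive libraries and to 0.251 to 0.446 CPM in the stimulated ones, which covers counting error only.

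The fits, the filter, 29 gene lists, the rule for naming genes and most of the alternatives were chosen before the data were examined. That plan left open whether the tables held counts or normalized values, and the test for normalized values was used. Genes above 1 CPM in at least 3 of the 6 libraries of a table were tested. DEX was compared with Control within each state by limma 3.58.1 in R 4.3.3, with a mean-variance trend and empirical Bayes, on log2(CPM + 1), a scale that understates the change of low genes. All tests were two-sided. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with 0.05 as the threshold. The difference of the DEX effect between the states was the interaction term of a fit over all 12 libraries, for genes passing the filter in both tables. Stimulated and naive cells were compared in the same fit. Fold changes are given in log2 units with their standard error (SE), and levels as mean ± standard deviation (SD) over 3 libraries.

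Lists with at least 5 tested members were tested with camera, which compares a list with all other tested genes, at a preset correlation between genes of 0.01. They were tested again with an estimated correlation and with fry, and adjusted over the lists tested in a state. Members were also adjusted over the list alone. Named genes were, for each state, the 10 largest rises and the 10 largest falls past the threshold with no overlap between groups and a mean above the median of the tested genes, leaving out unnamed gene models and antigen receptor segments. Where fewer than 5 qualified, the direction was filled to 5 by the smallest unadjusted p. Up to 4 members of each list with the smallest p, the corticosteroid receptors Nr3c1 and Nr3c2, the hormone-responsive genes Fkbp5, Tsc22d3 and Per1, and 10 genes that check the labels were named too. Of the genes that check the labels 1 is not reported here, and values of the other named genes are printed for part of them. For the difference between states the 5 largest in each direction were named among genes past the threshold with a mean over the 12 libraries above the median, with overlap between groups allowed. Where 5 or fewer members of a list passed in a direction, all of them were added after their values were seen, as was any gene past an adjusted p of 0.1 where 5 or fewer were.

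Alternatives covered other scalings (the sum of the listed genes, upper quartile, median ratio, trimmed mean), no filter or a filter at 5 CPM, pseudocounts of 0.1 and 10, limma without the trend or with robust empirical Bayes, the replicate number as a block, each library left out in turn, an adjusted p of 0.1, a minimum fold of 1.5, and a single fit over the 12 libraries. Scaling to the listed sum and an adjustment of each library's log values for transcript length, or for length and GC content, were added after seeing the data. Length was that of the longest transcript in the GENCODE vM21 annotation of GRCm38, which gave a length to 98.1% of the naive and 98.2% of the stimulated genes tested.

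The procedure was tested on simulated data. In each state a known 1.5-, 2- or 3-fold change was given to 200 of the real genes above its median expression. The spread of each gene was the value that limma with the trend and empirical Bayes gave for the real libraries, with counting error drawn separately. The procedure recovered 53.7, 98.5 and 100% of the known changes among 12163 naive genes, and 85.1, 100 and 100% among 12190 stimulated genes. Both simulated states together held 127, 130 and 125 genes changed in a single state by these folds, of which the interaction test recovered 39.4, 90.0 and 99.2% among 11484 genes. Of the calls, 6.15% were false in the naive, 5.94% in the stimulated and 5.21% in the interaction simulation. Among 200 lists with no shift, camera gave an unadjusted p under 0.05 to 0 in the naive and 1 in the stimulated simulation. Genes were simulated independently of each other, so this does not test camera on lists whose genes vary together between libraries. The simulated spread came from the trend model that was then fitted, so the choice of that model was not tested. No trend with transcript length was simulated either. No column of either table was left without a sample. Figures were drawn with matplotlib 3.10.9.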

Results

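Gene expression was measured in sorted CD8 T cells of mice labelled Control or DEX. The series title names exposure to a stress hormone around birth as the treatment. There were 3 libraries each of naive Control, naive DEX, stimulated Control and stimulated DEX cells. The inferred depth was 23.6, 21.6 and 20.4 M reads in naive Control libraries and 19.5, 14.02 and 14.3 M reads in naive DEX libraries. It was 9.16, 8.80 and 11.98 M reads in stimulated Control libraries and 7.25, 6.73 and 7.41 M reads in stimulated DEX libraries, so that low genes were measured least precisely there. Across genes, replicates of a group correlated at r = 0.973 to 0.986 in naive and 0.980 to 0.991 in stimulated cells. Libraries of different treatment correlated at 0.972 to 0.985 and 0.968 to 0.987. Levels are CPM, a unit inferred from the values, and changes are DEX minus Control on the log2(CPM + 1) scale.

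The comparison of naive cells asked whether perinatal exposure left a difference in resting CD8 T cells. No single gene passed the threshold, and among genes above the median expression those with the smallest p included memory-phenotype and heat shock genes. Eomes, a T-box transcription factor of memory CD8 T cells (chromosome 9, 118478212 to 118486132, GRCm38), was at 52.8 ± 4.73 CPM (SD, n = 3) in Control and 27.8 ± 3.61 CPM in DEX. Its log2 difference was -0.91 (SE 0.13, limma adjusted p = 0.154). Ly6c2, a surface marker of memory CD8 T cells, was at 108 ± 23.7 and 52.5 ± 2.52 CPM (-1.0, SE 0.15, adjusted p = 0.154). Cxcr3, a chemokine receptor, was at 26.8 ± 7.34 and 11.01 ± 0.886 CPM (-1.18, SE 0.18, adjusted p = 0.157). Il18rap, a subunit of the interleukin-18 receptor, was at 28.9 ± 8.79 and 12.2 ± 0.236 CPM (-1.14, SE 0.19, adjusted p = 0.223). In the other direction Hsph1, a cytosolic chaperone, was at 24.7 ± 6.68 and 58.0 ± 6.32 CPM (1.23, SE 0.19, adjusted p = 0.157). The co-chaperone gene Stip1 was at 80.4 ± 10.6 and 126 ± 8.19 CPM (0.65, SE 0.12, adjusted p = 0.235). Nfkbia, which encodes an inhibitor of NF-kappaB, differed by 0.60 (SE 0.11), Ccdc117 by 0.65 (SE 0.11), Ubfd1 by 0.61 (SE 0.11) and Cirbp, a cold-inducible RNA-binding protein gene, by -0.79 (SE 0.14). By the naming rule, which takes genes above the median expression whose groups do not overlap, these 10 genes had the smallest p in their direction. A gene below that expression limit, AC122428.2, had a smaller p.

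**Figure D1:**
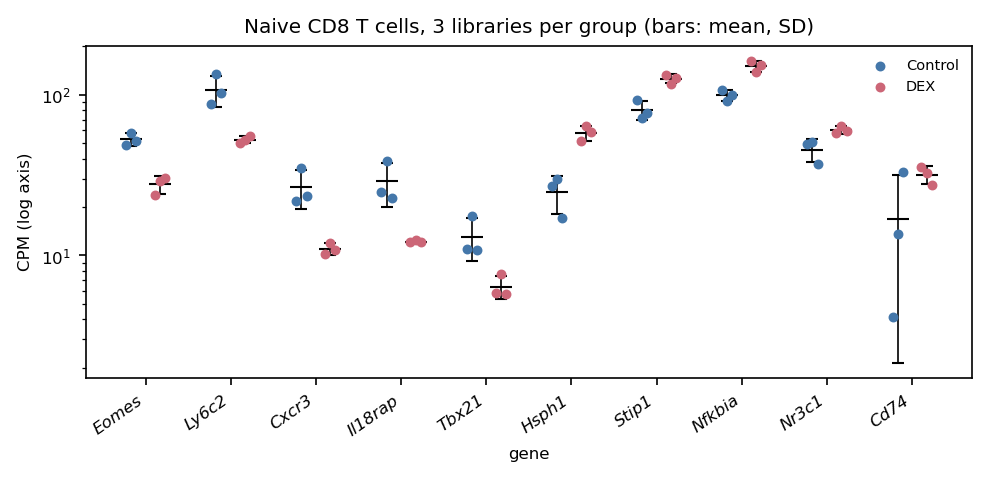
CPM (log axis) of 10 genes in the 3 Control and 3 DEX libraries of naive cells, with 1 point per library and bars for the mean and SD. Eomes, Ly6c2, Cxcr3, Il18rap and Tbx21 lay lower and Hsph1, Stip1, Nfkbia and Nr3c1 higher in every DEX library than in any Control library without passing the threshold, while the Control libraries of Cd74 spread from 4.13 to 33.1 CPM.

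Of the 24 memory-phenotype genes tested, 0 passed over all genes (14 of the 30 genes on this list are also on another). Adjusted over the list alone, 0 were higher and 6 lower (Eomes, Ly6c2, Cxcr3, Il18rap, Tbx21 and Il18r1). The list was lower by camera (median -0.07, adjusted p = 0.000524), with adjusted p = 0.693 with an estimated correlation. The heat shock list of 21 genes was higher (median 0.15, adjusted p = 0.00316), with adjusted p = 0.693 with an estimated correlation. None of its members passed over all genes. Adjusted over the list alone, 5 were higher (Hsph1, Hsp90aa1, Hspa8, Dnaja1 and Dnajb1) and 1 lower (Hspa1a). Beside these, camera called marker lists of other cells. The median difference was 0.98 for 10 B cell genes and 0.36 for 11 myeloid and dendritic cell genes, each higher at adjusted p = 0.000524, and at adjusted p = 0.693 with an estimated correlation. No member of either passed over all genes or adjusted over the list alone. The mean of these markers spanned 1.90 and 1.94 log2 units among the Control libraries, against differences between the groups of 0.77 and 0.86. Igkc, an immunoglobulin light chain gene, was at 228, 479 and 1392 CPM in the Control libraries and at 989 to 1188 CPM in DEX. Lyz2, a macrophage and neutrophil gene, was at 0.508, 4.36 and 10.9 CPM in Control and 8.20 to 21.7 CPM in DEX. Interferon-stimulated genes were lower (40 genes, median -0.06, adjusted p = 0.0188), with adjusted p = 0.863 with an estimated correlation. Chromatin modifier genes were higher (28 genes, median 0.08, adjusted p = 0.0287), with adjusted p = 0.693 with an estimated correlation. In both lists 0 members passed, over all genes or adjusted over the list alone. With each library left out the medians ran from 0.38 to 1.57 for B cell, 0.21 to 0.73 for myeloid, 0.06 (without Control library 2, adjusted p = 0.0122) to 0.17 for heat shock, -0.13 to -0.03 for memory-phenotype, -0.21 to 0.04 for interferon-stimulated and 0.05 to 0.12 for chromatin modifier genes. Without Control library 1 the adjusted p was 0.163 for the B cell, 0.371 for the myeloid, 0.117 for the chromatin modifier and 0.0506 for the memory-phenotype list. The chromatin modifier call was also lost without Control library 3 (0.268) or DEX library 3 (0.176), and the interferon call without Control library 3 (0.940) or DEX library 1 (0.710, median 0.04).

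Nr3c1, the glucocorticoid receptor gene (chromosome 18, 39410545 to 39519421), was at 45.5 ± 7.51 CPM in naive Control and 60.4 ± 3.15 CPM in naive DEX cells (0.41, SE 0.13, adjusted p = 0.844). The hormone-responsive genes Fkbp5 (-0.03, SE 0.12), Tsc22d3 (0.15, SE 0.13) and Per1 (0.24, SE 0.16) did not pass either. Of 21 glucocorticoid receptor target genes 0 passed over all genes, and 1, Nfkbia, was higher adjusted over the list alone (camera adjusted p = 0.271). Adjusted over the list alone, Eomes and Tbx21 were lower among 15 effector transcription factors and Il18rap among 24 cytokine receptors. Among 25 homing and adhesion genes Cxcr3 was lower and Itgae, an integrin of tissue-resident T cells, higher. No member passed over all genes or adjusted over the list alone among naive and quiescence (26 genes tested), cytotoxic (12), inhibitory receptor (13), immediate early (27), co-stimulatory (18) and cell cycle genes (43). The same held for glycolysis (22), oxidative phosphorylation (48), ribosomal protein (67), ribosome biogenesis (35), CD8 identity (15), CD4 T cell (8) and gamma-delta T cell genes (7). Camera gave the 17 lists not called adjusted p-values of 0.134 to 0.982. The test pointed lower while the median or mean did not for effector transcription factors (median 0.01, mean -0.13), cytokine receptors (0.01, -0.06), cytotoxic genes (0.04, 0.06) and ribosomal protein genes (0.02, 0.01). It pointed higher for immediate early genes (median -0.02, mean 0.05). Fry called 0 lists in a common direction, and heat shock and cytokine receptor genes in mixed directions (both adjusted p = 0.00154). Lists with under 5 tested members held 3 NK cell, 3 erythroid, 1 platelet, 2 stromal and 1 sex-linked gene, none past the threshold, and no mitochondrially encoded gene was listed.

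Among 12163 naive genes limma called 0 at an adjusted p under 0.05, with 675 at an unadjusted p under 0.05 where chance gives 608. The groups did not overlap for 10.98% of genes, where chance gives 10%. Robust limma called 0, and limma without the trend called 1, the long noncoding RNA AC122428.2. This gene, chosen after its values were seen, was at 4.14 ± 0.253 and 0.757 ± 0.0302 CPM (-1.55, SE 0.18, adjusted p = 0.0969 with the trend). The fit over 12 libraries called 26, 12 higher and 14 lower, among them Cxcr3, Eomes, Il18rap and Ly6c2 (adjusted p = 0.00807 each). That fit takes a single estimate of the spread from naive and stimulated libraries together. The median SE of the naive difference was 0.150 over the 11492 genes of that fit. It was 0.161 over the 12163 genes of the fit of the naive libraries alone, so the 2 medians cover different sets of genes.

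The comparison of stimulated cells asked the same of CD8 T cells after stimulation. In DEX cells 42 of 67 ribosomal protein genes rose and 4 fell, 24 of 48 oxidative phosphorylation genes rose, and 13 of 28 chromatin modifier genes fell. After adjustment for transcript length 22 ribosomal protein genes rose and 4 fell, 7 oxidative phosphorylation genes rose and 3 chromatin modifier genes fell. Camera called these lists, each at adjusted p = 0.535 with an estimated correlation, and the chromatin modifier call was lost after this adjustment (adjusted p = 0.163). Rpl27, a protein of the large ribosomal subunit (chromosome 11, 101442298 to 101445529), rose from 38.4 ± 6.21 to 95.1 ± 8.10 CPM (SD, n = 3). Its change was 1.30 (SE 0.12, limma adjusted p = 0.000969). Rps14 rose from 612 ± 39.5 to 1123 ± 175 CPM (0.86, SE 0.11, adjusted p = 0.0021), and Cox4i1, a subunit of cytochrome c oxidase, from 152 ± 7.04 to 222 ± 16.3 CPM (0.55, SE 0.08, adjusted p = 0.00284). Malat1, a long noncoding RNA kept in the nucleus (chromosome 19, 5795690 to 5802672), fell from 494 ± 208 to 133 ± 52.4 CPM (-1.88, SE 0.26, adjusted p = 0.00221). Kmt2d, a histone H3 lysine methyltransferase (chromosome 15, 98831669 to 98871204), fell from 523 ± 65.9 to 250 ± 78.8 CPM (-1.10, SE 0.17, adjusted p = 0.00284).

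The 10 largest rises by the naming rule were AC161763.1 (1.71), Olfr77 (1.70), Rps18-ps3 (1.497), Rpl27 (1.30), Snrpd2 (0.92), Rpl41 (0.90), Rps14 (0.86), Rps10 (0.86), Rplp1 (0.82) and AC123935.1 (0.80), with standard errors of 0.10 to 0.25. Several of these values are uncertain. Rps18-ps3 is a processed pseudogene, ribosomal protein genes share sequence with such copies, and the 2 AC gene models had no match in the annotation used. Of the processed pseudogenes tested, 160 rose and 12 fell. The 10 largest falls were Malat1 (-1.88), Palm3 (-1.49), Zbtb37 (-1.45), Clk1 (-1.22), Ogt (-1.21), Neat1 (-1.18), Ubn2 (-1.11), Kmt2d (-1.10), Snrnp48 (-1.09) and Leng8 (-1.08), with standard errors of 0.13 to 0.32. After adjustment for length Neat1 no longer passed (-0.68, adjusted p = 0.0831). Neat1 is another nuclear noncoding RNA, Clk1 a kinase of splicing factors, and Ogt the transferase that attaches N-acetylglucosamine to proteins. Palm3 overlaps Il27ra, so that its reads are uncertain too.

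**Figure D2:**
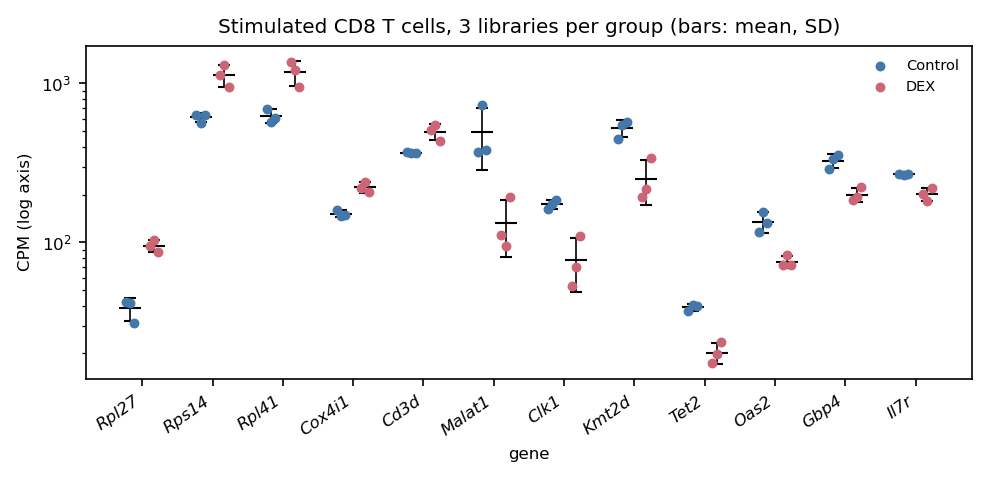
CPM (log axis) of 12 genes in the 3 Control and 3 DEX libraries of stimulated cells, with 1 point per library and bars for the mean and SD. In each gene all DEX libraries lay on one side of all Control libraries, with Rpl27, Rps14, Rpl41, Cox4i1 and Cd3d higher and Malat1, Clk1, Kmt2d, Tet2, Oas2, Gbp4 and Il7r lower.

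Of 67 cytosolic ribosomal protein genes 42 rose, 4 fell and 21 did not pass, and 49 rose and 4 fell adjusted over the list alone. The list was higher by camera (median 0.38, adjusted p = 1.87e-18), with adjusted p = 0.535 with an estimated correlation. The 4 that fell, chosen after their values were seen, were at 19.7 to 34.7 CPM in Control: Rpl9 (-0.61, SE 0.16), Rpl10 (-0.80, SE 0.22), Rps12 (-0.49, SE 0.14) and Rps13 (-0.73, SE 0.18). Of 48 oxidative phosphorylation genes 24 rose, 0 fell and 24 did not pass, and 33 rose adjusted over the list alone. Among them were Ndufa7 (0.67, SE 0.11) and Ndufv2 (0.51, SE 0.09) of respiratory complex I. Camera gave adjusted p = 8.73e-17, and adjusted p = 0.535 with an estimated correlation. Of 28 chromatin modifier genes 0 rose, 13 fell and 15 did not pass, and 15 fell adjusted over the list alone. Kmt2a (-0.78, SE 0.12) and the DNA demethylation enzymes Tet1 (-0.82, SE 0.15) and Tet2 (-0.92, SE 0.12) were among those that fell. After adjustment for length 3 of the 28 fell, with Kmt2a at -0.33, Tet2 at -0.59 and Tet1, no longer past the threshold, at -0.39 (adjusted p = 0.106). Camera gave adjusted p = 1.3e-05, and adjusted p = 0.535 with an estimated correlation. Of 15 CD8 identity genes 5 rose, also adjusted over the list alone, and 10 did not pass. They were the receptor complex genes Cd3d (0.43, SE 0.09), Cd3g (0.39, SE 0.09) and Cd247 (0.33, SE 0.08), with Thy1 (0.34, SE 0.10) and Cd2 (0.28, SE 0.08). Camera gave adjusted p = 0.0245, and adjusted p = 0.535 with an estimated correlation. Of 24 cytokine receptor genes 1 rose (Il10rb, 0.27, SE 0.08), 3 fell (Il7r, -0.43, SE 0.08; Il6st, -0.41, SE 0.09; Il18rap, -0.51, SE 0.12) and 20 did not pass, the same numbers adjusted over the list alone. Camera gave adjusted p = 0.0185, and adjusted p = 0.535 with an estimated correlation. After each library was adjusted for transcript length, camera called ribosomal protein (adjusted p = 5.93e-10), oxidative phosphorylation (9.58e-09) and glycolysis genes (0.0343). It did not call chromatin modifier (0.163), CD8 identity (0.190) and cytokine receptor genes (0.263). These values rest on the preset correlation, and none with an estimated correlation is given for them. No glycolysis gene passed after this adjustment (median 0.08). Thy1 (0.20), Cd2 (0.06), Il10rb (0.25), Il6st (-0.09) and Il18rap (-0.37) no longer passed. Rpl10, Rps12 and Il10rb kept their call in 1 of the 6 fits that leave out a library, and Thy1, Cd2 and Il10rb lost it after listed-sum scaling.

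**Figure D3:**
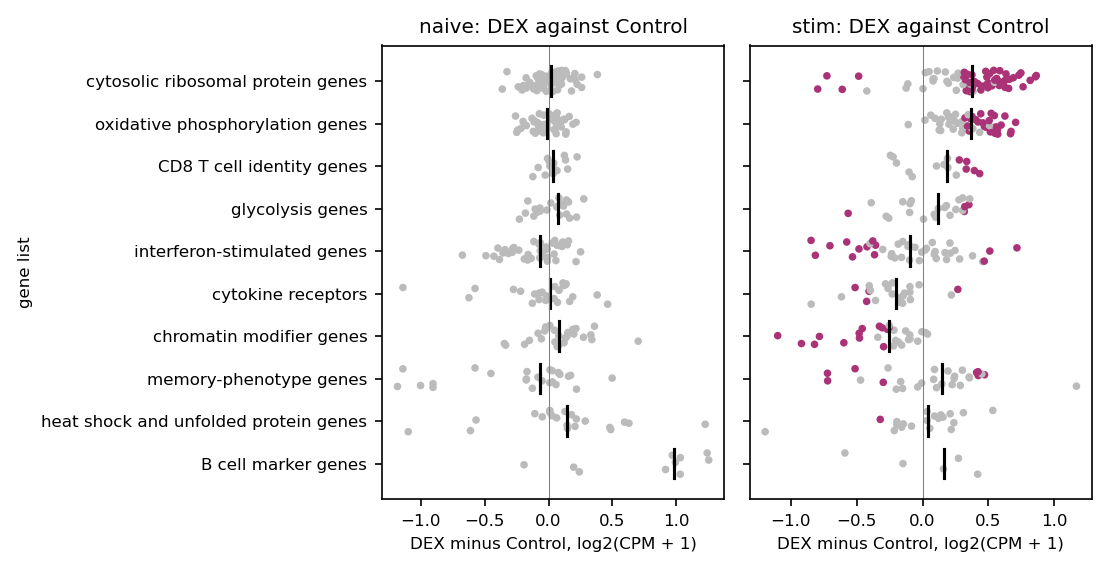
DEX minus Control on the log2(CPM + 1) scale for the members of 10 gene lists in naive (left) and stimulated cells (right), with 1 point per gene, purple for genes past the threshold, grey for the rest, and a black line at the median. In stimulated cells the medians were 0.38 for ribosomal protein, 0.37 for oxidative phosphorylation and -0.25 for chromatin modifier genes, and in naive cells no gene passed.

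Of the other lists, camera gave 16 not called adjusted p-values of 0.0609 to 0.995. Of 41 interferon-stimulated genes 3 rose, 10 fell and 28 did not pass, the same numbers adjusted over the list alone (camera adjusted p = 0.446). The rises were Isg20 (0.47, SE 0.15), Bst2 (0.51, SE 0.16) and Ifi27l2a (0.72, SE 0.16). Rnf213 (-0.85, SE 0.12), Oas2 (-0.81, SE 0.11), Gbp4 (-0.70, SE 0.10) and Ddx58 (-0.48, SE 0.08) had the smallest p among the falls. After adjustment for length 0 interferon-stimulated genes rose and 6 fell. Of 26 naive and quiescence genes 3 rose (Dapl1, 0.54; Klf2, 0.26; Ccr7, 0.26) and 7 fell, among them Bach2 (-0.40) and Bcl2 (-0.36), or 4 and 7 adjusted over the list alone. Of 29 memory-phenotype genes 4 rose (S100a10, 0.42; S100a11, 0.47; Crip1, 0.41; Lgals1, 0.42), also adjusted over the list alone. Another 4 fell by both counts, Ahnak (-0.72), Klrk1 (-0.72), Il18rap (-0.51) and Itgal (-0.30). Of 17 co-stimulatory receptors Cd2 (0.28) and Tnfrsf18 (0.39) rose and Cd28 (-0.66), Tnfsf8 (-0.40) and Slamf6 (-0.38) fell, also adjusted over the list alone. Of 23 glycolysis genes Ldha (0.35), Eno1 (0.32) and Aldoa (0.32) rose and Pfkp fell (-0.57), also adjusted over the list alone. After adjustment for length Bach2 was at -0.08 (adjusted p = 0.574) and Bcl2 at -0.09 (adjusted p = 0.476). Of the genes named in these lists, Rnf213, Oas2, Gbp4, Ddx58, Klrk1, Cd28 and Tnfsf8 still passed then and the others did not, although Crip1 (0.29) and Eno1 (0.23) stayed within 1.5 times of their change before. Isg20, Bst2, Klf2, Ccr7 and Slamf6 kept their call in 1 of the 6 fits that leave out a library. Isg20, Bst2, Klf2, Ccr7, Cd2 and Tnfrsf18 lost it after listed-sum scaling, Slamf6 after upper quartile scaling, and Itgal after upper quartile, median ratio and trimmed mean scaling.

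Of 35 ribosome biogenesis genes 4 rose (Eif5a, 0.41; Phb, 0.57; Pes1, 0.35; Rrp9, 0.36) and 3 fell (Ppan, -0.39; Cad, -0.31; Polr1a, -0.31, which was 0.02 after adjustment for length), or 6 and 5 adjusted over the list alone. Of 30 cell cycle genes E2f1 (0.96), Pcna (0.31) and Kif23 (0.58) rose and Tpx2 fell (-1.04), or 2 and 1 adjusted over the list alone. Of 28 immediate early genes Rel (-0.65), Nfkbiz (-0.75) and Egr1 (-0.30) fell, and of 14 effector transcription factors Ikzf3 (-0.35) and Hif1a (-0.30). Of 21 homing genes Itga4 (-0.74) and Itgal (-0.30) fell and Ccr7 rose. Adjusted over the list alone, 0 rose and 2 fell in each of these 3 lists. Single calls were Btla (-0.59) of 14 inhibitory receptor genes, Hsp90b1 (-0.32) of 20 heat shock genes, Srgn (0.26) of 17 cytotoxic genes and Tnfsf8 of 6 CD4 T cell genes. Adjusted over the list alone these lists had 1, 1, 0 and 2 calls. Of 5 B cell genes 0 passed over all genes, and Cd79b was higher and Cd22 lower adjusted over the list alone. In lists too small to test, Cst3 (0.42) rose among 4 myeloid genes and Tfrc (-0.41) fell among 2 erythroid genes. The Y-linked Ddx3y (-0.55), Kdm5d (-0.49) and Uty (-0.63) fell among 4 sex-linked genes. None of 4 NK cell, 2 gamma-delta, 2 platelet and 1 stromal gene passed, and no mitochondrially encoded gene was listed. The test pointed higher while the median or mean did not for homing (median -0.03, mean -0.08), co-stimulatory (0.01, -0.06), cell cycle (0.03, -0.04) and heat shock genes (0.04, -0.02). Of the single genes called in these lists, Pes1, Ppan, E2f1, Nfkbiz, Btla, Hsp90b1, Tnfsf8 and Ddx3y still passed after adjustment for length and the others did not, although Phb (0.44), Kif23 (0.61), Tpx2 (-0.93) and Uty (-0.46) stayed within 1.5 times of their change before. Pcna, Kif23, Egr1, Hif1a, Ccr7 and Tfrc kept their call in 1 of the 6 fits that leave out a library. Cad, Polr1a, Egr1, Hif1a, Itgal and Tfrc lost it after upper quartile, median ratio and trimmed mean scaling, and Rrp9, Kif23, Srgn and Ccr7 after listed-sum scaling.

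Nr3c1 fell from 66.9 ± 3.11 CPM in stimulated Control to 52.7 ± 5.70 CPM in stimulated DEX cells (-0.35, SE 0.10, adjusted p = 0.03). The call was lost after upper quartile or trimmed mean scaling and after adjustment for length (-0.11, SE 0.09, adjusted p = 0.470), and kept in 1 of the 6 fits that leave out a library. Of 21 glucocorticoid receptor target genes 0 rose, 3 fell and 18 did not pass, with 0 and 2 adjusted over the list alone (camera adjusted p = 0.693). Those that fell were the clock gene Per1 (-0.46, SE 0.15, also kept in 1 of these 6 fits and lost under upper quartile, median ratio and trimmed mean scaling), the interleukin-7 receptor gene Il7r and the pro-apoptotic gene Bcl2l11 (-0.43, SE 0.10). After adjustment for length Per1 (-0.33) and Bcl2l11 (-0.27) did not pass. Fkbp5 (0.12, SE 0.12) and Tsc22d3 (-0.10, SE 0.09) did not pass.

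Across protein-coding genes the change in stimulated cells followed transcript length (Spearman's rho = -0.578 across genes, which are not independent replicates). Above 50 CPM rho was -0.721 over 3097 genes of any type, and among protein-coding genes of naive cells it was 0.0336. Among the 2022 protein-coding genes with the shortest transcripts 450 rose and 24 fell (median 0.21). Among the 2019 protein-coding genes with the longest 8 rose and 810 fell (median -0.32). Over called genes of any type, the median length was 1233 nt for those that rose and 5692 nt for those that fell. Those that rose included 160 processed pseudogenes, and those that fell 12. In each library's deviation from the mean of the 6, rho with length was 0.321, 0.511 and 0.483 in the stimulated Control and -0.437, -0.497 and -0.196 in the stimulated DEX libraries. It was -0.197, 0.209 and -0.137 in the naive Control and -0.0568, -0.0562 and 0.164 in the naive DEX libraries, so replicates of a group also differed along length. After adjustment for length 767 genes passed (291 higher, 476 lower), of which 667 had passed in the same direction before.

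**Figure D4:**
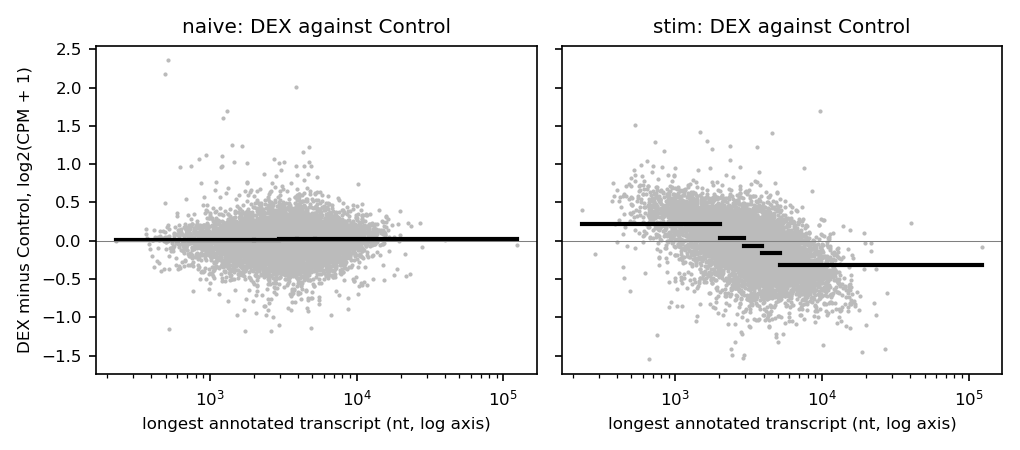
DEX minus Control on the log2(CPM + 1) scale against the length of the longest annotated transcript (log axis) for protein-coding genes in naive (left) and stimulated cells (right), with 1 grey point per gene and black lines for the median of each of 5 groups of genes by length. The medians ran from 0.21 in the shortest to -0.32 in the longest group in stimulated cells and from 0.01 to 0.02 in naive cells.

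Among 12190 genes limma called 2338, 857 higher and 1481 lower (36.7% higher). The groups did not overlap for 37.4% of genes, where chance gives 10%. The split followed the scaling, with 53.1% of calls higher after upper quartile, 49.5% after median ratio, 50.2% after trimmed mean and 24.3% after listed-sum scaling, the last of which put the median of all genes at -0.10. The count was 10 without the trend in limma's spread model (2414 at an adjusted p under 0.1), 783 without the filter and 759 at 1.5-fold or more. It was 615 and 588 without Control libraries 2 and 3, and 1267, 872 and 3794 without DEX libraries 1, 2 and 3. Of the 10 largest rises 9 passed in every fit that leaves out a library, as did 9 of the 10 largest falls and 39 of all 97 named genes past the threshold. Without the trend 1 of these 97 passed, and after adjustment for length 46 of the 95 with a known length. Without Control library 2 the CD8 identity (0.0610) and cytokine receptor lists (0.0616) lost their call, the latter also without DEX library 3 (0.158). Fry called the ribosomal protein and CD8 identity lists (both adjusted p = 0.0463) in a common direction and 18 lists in mixed directions.

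The difference of the DEX effect between the states was tested directly for 11492 genes. The tables also differ in their T cell receptor and sex-linked genes, so that a difference between states is not separated from other differences between the tables, the mice used included. The test passed for 324, 88 with a higher effect in stimulated cells and 236 with a lower one. Among genes above the median expression, the largest of the first were Rps18-ps3 (difference 1.92, SE 0.42), Rpl27 (1.5, SE 0.21), Ly6c2 (1.29, SE 0.21), Cxcr3 (1.15, SE 0.24) and Ifi27l2a (1.11, SE 0.22). The largest of the second were Zbtb20 (-1.66, SE 0.32), Hsph1 (-1.42, SE 0.28), Clk4 (-1.26, SE 0.24), Ubn2 (-1.25, SE 0.25) and Clk1 (-1.24, SE 0.25). Their adjusted p-values were 0.0096 to 0.0282. For Ly6c2, Cxcr3 and Hsph1 the naive difference was the larger, at -1.0, -1.18 and 1.23 against 0.29, -0.04 and -0.20 in stimulated cells. These genes did not pass in the fit of the naive libraries alone, and the interaction test takes its spread from both states together. The count was 5 without the trend, 31 after adjustment for length, 14 for length and GC, and 919 at an adjusted p under 0.1. It was 904 and 133 without naive Control libraries 2 and 3, 111, 186 and 18 without naive DEX libraries 1, 2 and 3, 8 and 11 without stimulated Control libraries 2 and 3, and 63, 15 and 1213 without stimulated DEX libraries 1, 2 and 3.

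Fold changes of the states correlated weakly across these genes (Pearson's r = 0.0389, Spearman's rho = 0.0438, genes not being independent replicates). Of 1852 genes called in either state in the fit over 12 libraries, 904 (48.8%) had the same sign in both, against 51.3% of all genes tested in both. The correlation was 0.221, -0.223 and 0.0588 without naive Control libraries 1, 2 and 3, and -0.0305, 0.00649 and 0.131 without naive DEX libraries 1, 2 and 3. It was 0.0601 without stimulated DEX library 2, and within 1.5 times of the full value without the other stimulated libraries.

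Stimulated and naive cells were compared to check the labels, with both tables taken to share the unit. Cd44, an adhesion receptor that marks activated T cells, was at 7.28 ± 1.39 CPM in naive and 27.5 ± 1.86 CPM in stimulated Control cells. Ly6c2 was at 108 ± 23.7 and 719 ± 65.7 CPM and the proliferation gene Mki67 at 16.8 ± 8.64 and 5.80 ± 0.518 CPM. Gzmb, a cytotoxic granule protease, ranged from 2.5 to 4.98 CPM over the naive and from 15.9 to 91.7 CPM over the stimulated libraries. The genes that check the labels did not all go the same way, so these values do not establish activation. Besides the lower Mki67, Cd69 was at 74.6 to 91.9 CPM over the stimulated and 88.5 to 126 CPM over the naive libraries. Ifng (0.276 to 1.75 CPM) and Il2ra (0.675 to 3.51 CPM) were low in the stimulated libraries. Limma called 6955 genes in Control (5499 higher in stimulated cells, 1456 lower) and 7564 in DEX (5408 and 2156), around a median shift of all genes of 0.34 and 0.30. The state is confounded with the sort gate, the depth and the filter of the table, and with the T cell receptor and sex-linked genes. Trbv12-1 was at 619 to 872 CPM in naive and 16.7 to 19.4 CPM in stimulated libraries. Xist was at 299 to 879 CPM in naive libraries and not listed in the stimulated table, and Ddx3y was at 36.8 to 70.9 CPM in stimulated libraries and not listed in the naive table.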

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

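Of the tests below, the splits of libraries for the difference between states and for stimulated against naive cells, and the test of library handling, were set before their results were seen, and the others, with the grouping of splits by the stimulated libraries, only after.

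The DEX effect differed between stimulated and naive cells for 324 genes by the interaction test, which is what marked these results. Among genes above the median expression the largest differences were those of Rps18-ps3 (1.92), Rpl27 (1.5), Ly6c2 (1.29), Cxcr3 (1.15), Ifi27l2a (1.11), Zbtb20 (-1.66), Hsph1 (-1.42), Clk4 (-1.26), Ubn2 (-1.25) and Clk1 (-1.24). Of 100 splits of the libraries within each state, 3 gave as many genes, the real split included, and the highest of the others gave 827. These 3 were among the 7 splits that kept the stimulated libraries as treated, while the other 93 gave at most 1 gene. The splits thus follow the effect in stimulated cells and are too few to tell a difference between states from chance, and without stimulated Control library 2 the count was 8. The test does not separate cell state from other differences between the tables, whose receptor and sex-linked genes differ.

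In stimulated DEX cells long transcripts fell and short transcripts rose. A trend with annotated transcript length as the whole cause was argued against for part of the calls. After each library was adjusted for length 667 genes passed in the same direction as before, where the threshold allows 38.4 false calls. Their median size was 0.65 before and 0.53 after (median SE 0.13 and 0.11). That bound covers random error only, and length was that of the longest annotated transcript, not of the transcript expressed. A length trend that this measure misses stays open for these calls. Counting noise from fewer reads in the DEX libraries was argued against by rho = -0.721 with length above 50 CPM, where such noise is small. The inferred depth itself parted the stimulated groups, at 8.80 to 11.98 M reads in Control and 6.73 to 7.41 M in DEX. A cause that goes with depth in another way was not tested. For the 1630 calls lost as their median size went from 0.44 to 0.23 (median SE 0.11 and 0.099), the length trend and the treatment cannot be told apart, because the trend parts the groups. A length trend was not absent within groups: the main axis of variation among replicates followed length at an absolute rho of 0.269 in stimulated Control and 0.287 in stimulated DEX. It was 0.162 in naive Control and 0.125 in naive DEX. Library preparation or RNA handling that differs between libraries may contribute and stays open: the main axis of variation among replicates correlated with the stimulated change at an absolute r of 0.464 in naive Control, 0.058 in naive DEX, 0.273 in stimulated Control and 0.461 in stimulated DEX, the highest between the bounds set in advance, and a change of RNA composition by the treatment stays open too.

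In naive DEX cells camera called the B cell and myeloid marker lists higher and the memory-phenotype list lower with 0 members past the threshold, calls that went to adjusted p = 0.693 with an estimated correlation and to 0.163, 0.371 and 0.0506 without Control library 1. RNA of other cells that varies between libraries is a candidate explanation for the marker lists, since their range among the 3 Control libraries was at least 2.26 times the difference between groups. Within Control Igkc ranged from 228 to 1392 CPM and Lyz2 from 0.508 to 10.9 CPM, although the gate took CD8 cells only. In stimulated cells 5 B cell and 4 myeloid markers passed the filter, but Igkc was at 0.0835 to 0.297, Cd79a at 0.148 to 0.568 and Lyz2 at 0 to 0.501 CPM. Other B cell markers were not that low. Ighm was at 465 to 605 CPM in the stimulated and 425 to 1908 CPM in the naive libraries. Cd74 was at 3.34 to 5.13 CPM in the stimulated libraries. The markers of the B cell list thus did not move together between the tables. A lower share of CD8 T cells was argued against for the 6 memory-phenotype genes that were lower adjusted over their list, because the CD8 identity genes did not fall (median 0.0359, SD 0.0896). The median of the 6 genes was -0.95, but they were picked for being lower in these data, which in part set this gap. The median of all 24 memory-phenotype genes tested was -0.07. A lower share of memory-phenotype cells in the gate and an effect of the treatment within cells stay open and were not tested.

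The receptor and sex-linked genes part the naive from the stimulated libraries. Swapped state labels were argued against, since the lowest naive value of Trbv12-1, part of the OT-I receptor, was 31.9 times its highest stimulated value. Mice of different sex in the 2 tables may explain the sex-linked genes: Xist in naive and Ddx3y in stimulated libraries were never under 36.8 CPM. Mice without the OT-I receptor may explain the diverse receptors of the stimulated libraries, where Trbv12-1 made up at most 5.36% of the sum of 22 beta-chain variable genes. Neither explanation could be checked against the labels, which give no sex and name OT-I for naive cells only, and no further explanation was tested.

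The counts of genes and lists were set against other splits of the same libraries. For DEX against Control, 10 of 10 splits of the naive libraries gave as many genes (real 0, highest other 1), and 1 of 10 splits of the stimulated ones (real 2338, highest other 0). The naive outcome was fixed beforehand, since every split gives at least 0 genes. For gene lists 5 of 10 splits gave as many in naive cells (real 6, highest other 10) and 6 of 10 in stimulated cells (real 5, highest other 6). For stimulated against naive cells 1 of 10 splits gave as many in Control (real 6955, highest other 0) and 1 of 10 in DEX (real 7564, highest other 0). With 10 splits no share under 0.05 can be reached, so the counts of genes cannot be told from chance this way. The numbers of lists called were no larger than in many other groupings of the libraries. For the correlation of fold changes between states, 72 of 100 splits gave an absolute r as large as 0.0389, the highest other being 0.432, so that chance cannot be excluded.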

How the results depend on the processing

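The listed-sum scaling and the adjustments for transcript length and GC were chosen after seeing the data, and all other settings before. Over the settings planned, named genes and lists kept their direction and side of the threshold 3763 times, no longer passed it 442 times, newly passed it 34 times and reversed 35 times. Over those added, the numbers were 661, 130, 2 and 8. None of the naive genes among them was past the threshold, so these had no call to lose. Of the 97 named genes past it in stimulated cells, 39 kept their call in every fit that leaves out a library. Where a cause is not given below, the cause was not tested.

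For naive genes past the threshold (0), limma without the trend gave 1, an adjusted p under 0.1 gave 1 and the fit over the 12 libraries gave 26. Naive lists (6 called) went to 0 with an estimated correlation, 0 by fry, and 2 to 7 with each library left out. Stimulated genes (2338) went to 783 with no filter, 10 without the trend, 767 adjusted for length, 823 for length and GC, 759 at 1.5-fold or more, and 588 to 3794 with each library left out. Stimulated lists (5 called) went to 3 adjusted for length, 3 for length and GC, 0 with an estimated correlation, 2 by fry, and 3 to 6 with each library left out. The difference between states (324) went to 5 without the trend, 31 adjusted for length, 14 for length and GC, 919 at an adjusted p under 0.1, and 8 to 1213 with each library left out. The correlation of fold changes ran from -0.223 to 0.221 with each library left out. Stimulated against naive cells kept its count within 1.5 times in all settings run.

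Of the results that reversed, Polr1a in stimulated cells and the naive interferon list had passed the threshold, and the others had not. In naive cells Itgb3 was -0.0232 by listed-sum, -0.0257 by upper quartile, -0.00679 by median ratio and -0.00607 by trimmed mean scaling. With each naive library left out, ranges were -0.0901 to 0.0974 for Itgb3, -0.132 to 0.716 for Tyrobp, -0.668 to 0.175 for Tcrg-C1, -0.259 to 0.791 for Tcrg-C4, -0.133 to 0.0498 for Fkbp5 and -0.0936 to 0.0717 for Cd8b1. They were -0.0147 to 0.252 for Cd2, -0.0752 to 0.282 for Pecam1, -0.533 to 0.244 for Xist, -0.0125 to 0.189 for Trdc, -0.274 to 0.0394 for Pdgfrb and -0.207 to 0.0359 for the median of the list interferon-stimulated genes, naive. In stimulated cells Pecam1 was 0.0295 by upper quartile, 0.0158 by median ratio and 0.018 by trimmed mean scaling, and Klre1 was -0.11 with a pseudocount of 0.1. Adjusted for length, and for length and GC, Xcl1 was -0.067 and -0.0293 and Cd69 0.0603 and 0.2001. Polr1a was 0.0242 adjusted for length, and Ighm -0.00365 and Cd44 0.0137 adjusted for length and GC. With each stimulated library left out, ranges were -0.0935 to 0.00625 for Pecam1, -0.364 to 0.604 for Klre1, -0.0215 to 0.188 for Trdc, -0.329 to 0.226 for Ifng, -0.771 to 0.456 for Gzmb, -0.496 to 0.0235 for Car2 and -0.28 to 0.118 for Tcrg-C2.

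Replicate numbers were not taken to pair the samples, since same-numbered libraries deviated together at r = 0.0819, -0.107 and -0.0809 in naive and 0.0691, 0.0218 and 0.0932 in stimulated cells. With the replicate number as a block the counts were 0 for naive, 2841 for stimulated, 333 for the difference between states, 7001 and 7649 for stimulated against naive cells in Control and DEX, and 5 lists in each state. The count test on recovered reads was not run, because the values did not give whole reads. Depth limits low genes most in the stimulated libraries, where 3 reads correspond to up to 0.446 CPM.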

Other observations

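No hypothesis is added in this part, and its values were looked up only after the main results were seen. Stimulated libraries were set beside markers of effector and resting cells. Ifng was at 0.984 ± 0.419 CPM in Control and 0.973 ± 0.743 CPM in DEX, and Gzmb at 40.3 ± 20.5 and 45.5 ± 40.6 CPM (SD, n = 3), with neither past the threshold. Cd8a was at 393 to 502 CPM over the naive and 1142 to 1282 CPM over the stimulated libraries, and Cd69, an early activation marker, at 88.5 to 126 and 74.6 to 91.9 CPM. Cd8b1 was at 991 to 1247 CPM over the naive and 1047 to 1362 CPM over the stimulated libraries, Cd4 at 1.44 to 6.93 and 0 to 0.81 CPM, and Il2ra, a subunit of the interleukin-2 receptor, at 0.441 to 1.64 and 0.675 to 3.51 CPM. Nr3c2, the mineralocorticoid receptor gene, was at 0 to 0.454 CPM in the stimulated libraries and not listed in the naive table. Igkc was at 0.0835 to 0.297 CPM in the stimulated libraries, far below its naive level, whereas Ighm was at 465 to 605 CPM there.

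The antigen receptor genes listed differed between the tables. Trbv12-1 was the 1 beta-chain variable gene listed for naive cells, against 22 for stimulated cells, where it made up 3.56 to 5.36% of their sum. Immunoglobulin variable genes numbered 100 in the naive and 52 in the stimulated table. These numbers may follow in part the filter of each table, which is not given in the sources used here.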
